A study of Homo sapiens with 36 samples.

How the data were processed

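Expression was measured by polyA-selected RNA sequencing (a Smart-seq2 style protocol) in 36 libraries of K562 cells, 3 for each of 12 combinations of 3 oxygen levels and 4 times. The labels place the plates in incubators of 1%, 5% or 21% oxygen and state a passage at 3 d. The FPKM values were made by the authors with TopHat and the Cufflinks suite (Cuffnorm), whose versions, genome build and annotation are not given in the sources used here, so no coordinates are reported. The gene table held 21950 genes and 41726 transcripts were listed in a further table, which was used only for checks. Neither holds counts, so depth and counting error are unknown. Relative depth was estimated from the values that weakly expressed genes take, and lay between 0.525 and 1.57 in 35 libraries. It could not be estimated for replicate 3 of 1% oxygen at 3 d, the shallow library, which was kept in all tests unless stated otherwise.

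Groups were taken from the labels. Values were used as log2 of FPKM plus a pseudocount of 1. Genes with a mean FPKM of at least 1 over all libraries were tested, 10625 in number. A single limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 12 groups, a trended prior and 24 residual degrees of freedom served all comparisons, with two-sided moderated tests and Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. The comparisons were 1% and 5% against 21% oxygen at each time and averaged over the 4 times with equal weight, 1% against 5% averaged, each later time against 6 h in 21% oxygen, and moderated F tests of whether the differences from 21% varied with time. These 16 comparisons of single contrasts and tests of variation, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The comparisons of 1% with 5% oxygen at each of the 4 times were added after the data were seen. The p-values measure only the spread between replicates within groups, pooled over all 12 groups.

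Of 32 lists of genes fixed in advance, 31 had at least 3 members that passed the filter and were tested with camera (limma) at its preset correlation of 0.01, adjusted over the lists within a comparison. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. The remaining list, of mitochondrially encoded genes, had 0 members in the table. Members that passed were counted over all genes tested and over the list alone. The overlap of the 1% and 5% responses, which share their 21% libraries, was set beside simulated data with no effect and beside controls divided in sets of 6 libraries.

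Genes were named by a rule with 5 parts. The first was a fixed set of 29, a few of which are not reported here; the rest of the set is CA9, VEGFA, ADM, BNIP3, PDK1, EGLN3, NDRG1, SLC2A1, SLC2A3, LDHA, PGK1, HK2, P4HA1, HIF1A, EPAS1, HMOX1, TFRC, HBG1, HBA1, HBZ, ALAS2, SCD, HMGCS1, TXNIP, MYC, NDUFA4L2 and COX4I2. For 1% and 5% against 21% oxygen averaged over time, the rule took the 10 largest rises and 10 largest falls past the threshold with a mean FPKM of at least 5 in the higher level and the same sign at all 4 times. For single times, 1% against 5% averaged and the times in 21% oxygen, it took the 5 largest rises and 5 largest falls past the threshold with a mean FPKM of at least 5 in the higher group and no overlap of 3 libraries against 3. For the tests of variation with time it took the 10 smallest adjusted p values with a mean FPKM of at least 5 in a group, and for each list up to 4 members with the smallest adjusted p. The text leaves out some genes the rule names.

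The procedure was tested on simulated data, in 5 runs of 200 changed genes, where between 3.93% and 6.18% of calls were false. The simulated values were independent and each gene had the same spread in all libraries. That share therefore does not cover a library that deviates as a whole, such as the shallow one. Alternatives tried were a smaller pseudocount, no filter or a stricter one, a fit on the compared groups only and the replicate number as a block. Others were quantile normalization, rescaling to TPM, array weights, an added fold limit, and leaving out in turn each library of the groups compared. Leaving the shallow library out of the whole fit and correcting each library for GC content and transcript length were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.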

Results

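The libraries came from K562 cells, a human erythroleukemia line that makes embryonic and fetal globins, kept in 21%, 5% or 1% oxygen for 6 h, 24 h, 3 d or 6 d. Each of the 12 combinations had 3 libraries, 36 in all. Plates of each oxygen level stood in incubators of that level, so that oxygen level and incubator cannot be separated. Gene expression was given as FPKM, a fragment count scaled for transcript length and library size, for 21950 genes. The depth of the libraries in reads is unknown, because the tables hold no counts. Relative to each other, 35 libraries lay between 0.525 and 1.57 in depth, a 2.99-fold range estimated from the values that single fragments give to weakly expressed genes. The remaining library, replicate 3 of 1% oxygen at 3 d, stood apart. It had 7220 genes above 0 where the others had 14512 to 19543, and it listed 0 for 429 of 3695 genes whose median was over 20 FPKM, where each of the others listed 0 for at most 7. It is called the shallow library here, and counts without it stand beside the main ones. Genes of olfactory receptors, a few of which are known to be expressed in blood cells, served as a rough measure of background: of the 394, 14.7% to 27.7% were above 0 in the libraries of 6 h, 13.2% to 67.3% at 24 h, 33.8% to 70.1% at 3 d apart from the shallow library (2.28%), and 23.6% to 74.6% at 6 d. In 5% oxygen the share was 66% to 74.6% at 6 d, and in 1% oxygen it was 23.6% to 37.1%. That share thus differed between libraries at 24 h and later.

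The first question was which genes 1% oxygen changed relative to atmospheric oxygen. Genes known to be induced by the hypoxia-inducible factors (HIF) were higher in 1% oxygen. Averaged over the 4 times, EGLN3, a prolyl hydroxylase that marks HIF for destruction, rose by 2.41 on the log2 scale (SE 0.0944, adjusted p 2.92e-17, 12 libraries against 12). PDK1, a kinase that inhibits pyruvate dehydrogenase in mitochondria, rose from 5.919 ± 1.19 FPKM (SD, n = 3) in 21% oxygen at 6 d to 62.21 ± 6.95 in 1%, and its average log2 difference was 2.08 (adjusted p 2.42e-15). CA9, a carbonic anhydrase of the cell surface, was listed at 0 in all 3 libraries of 21% oxygen at 3 d and reached 32.9 ± 3.97 FPKM (SD, n = 3) in 1% oxygen. BNIP3, a receptor for the removal of mitochondria, rose from 70.33 ± 4.14 to 470.5 ± 23.1 FPKM (SD, n = 3) at 6 d. Among the other largest average rises were ANKRD37 (2.26), PFKFB4 (1.84), which makes an activator of glycolysis, BHLHE40 (1.80), a transcriptional repressor, and the aldolase ALDOC (1.76). Of the 22 genes of glycolysis and glucose uptake, 19 rose, among them LDHA, which makes lactate (1.18), PGK1 (0.99), the glucose transporters SLC2A1 (0.81) and SLC2A3 (0.88) and HK2 (0.91), while 1 fell: PFKM, a phosphofructokinase, named after its values were seen (-0.50). The list's median log2 difference was 0.80 (camera adjusted p 5.2e-29, 0.000788 with an estimated correlation), and adjusted over the list alone 19 rose and 1 fell. Of 28 other hypoxia-induced genes, 23 rose, including the collagen prolyl hydroxylase P4HA1 (1.72), VEGFA (0.64), which drives blood vessel growth, ADM (0.93) and NDRG1 (0.90), and the hormone gene STC2 fell (-0.47). Their median was 0.83 (camera adjusted p 9.12e-27, 0.000347 with an estimated correlation), and adjusted over the list alone 24 rose and 1 fell. Of the HIF subunits themselves, EPAS1 (HIF-2α) rose by 0.87, and HIF1A had a log2 difference of -0.06 (SE 0.0805, adjusted p 0.588). NDUFA4L2, a HIF target, did not pass the test (adjusted p 0.749), and HMOX1 and COX4I2 were below the expression filter.

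Genes of the red cell program were also higher in 1% oxygen. ALAS2, the first enzyme of heme synthesis in erythroid cells, stood at 283.5 ± 15.9 FPKM (SD, n = 3) in 1% oxygen at 6 d against 11.97 ± 0.19 in 21%, and its average log2 difference was 1.64 (SE 0.0722, adjusted p 4.17e-16). The embryonic globin HBZ stood at 18430 ± 2080 against 1175 ± 51.6 FPKM (SD, n = 3) at 6 d, with an average of 1.14. SLC4A1, the anion exchanger of the red cell membrane, rose by 1.65, the water channel AQP10 by 1.61, and TFRC, the transferrin receptor that takes up iron, by 0.78. The near-identical fetal and adult globin copies HBG1 (0.36) and HBA1 (0.83) rose on average, though short reads cannot place all fragments between such copies. Among 21 globin and erythroid membrane genes 11 rose and 1 fell (median 0.28, camera adjusted p 8.93e-08, 0.0159 with an estimated correlation). Adjusted over the list alone, 12 rose and 1 fell. The average came from the later times: the list's median was -0.05 at 6 h, -0.36 at 24 h (camera adjusted p 0.265, 5 genes lower and 1 higher), 0.21 at 3 d and 1.84 at 6 d. Among 13 heme synthesis genes 7 rose, with FECH, which inserts the iron, at 0.54 (list median 0.26, camera adjusted p 7.68e-05, 0.0324 with an estimated correlation). Adjusted over the list alone, 7 rose and 1 fell. Of 11 erythroid transcription factors, MYB fell (-0.79) and none rose (camera adjusted p 0.897). Of 5 megakaryocyte markers, the tubulin TUBB1 (1.09), the collagen receptor GP6 (0.40) and CD9 (0.65) rose (camera adjusted p 0.0037, 0.0359 with an estimated correlation).

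Sterol genes rose in 1% oxygen and genes of ribosome biogenesis fell. Of 25 cholesterol synthesis genes 20 rose, among them HMGCS1, an early enzyme of the pathway (0.93, SE 0.0812) and the squalene epoxidase SQLE (0.60), with a list median of 0.38 (camera adjusted p 4.2e-16, 0.0159 with an estimated correlation). Adjusted over the list alone, 20 rose and 1 fell. Of 17 genes of fatty acid synthesis 8 rose, SCD, a desaturase that itself uses oxygen, among them (0.48), but the list's camera adjusted p of 0.00534 became 0.361 with an estimated correlation. TXNIP, which restrains glucose uptake, rose by 0.93. MYC fell (-0.37, SE 0.0382, adjusted p 1.97e-08), and 21 of 28 genes of ribosome biogenesis and MYC fell with it (median -0.38, camera adjusted p 2.4e-10, 0.0243 with an estimated correlation; 25 fell adjusted over the list alone), among them LYAR (-0.57) and PA2G4 (-0.39). Genes of the mitochondria were lower as single genes: 36 of 44 of complex I, 31 of 39 of complexes II to V, 47 of 58 of the mitochondrial ribosome and 15 of 21 of the TCA cycle fell. Examples were NDUFAF3 (-0.63), an assembly factor of complex I, ATP5G1 (-0.57), MRPL34 (-0.66) and the pyruvate carrier MPC1 (-0.57). Their camera calls ended with an estimated correlation (adjusted p 0.274, 0.354, 0.177 and 0.354), as did that of the cytosolic ribosomal proteins (23 of 70 lower, median -0.18; 0.673). These averages came mostly from 24 h and 3 d: the complex I median was -0.63, -0.80 and, at 6 d, -0.02 (camera adjusted p 0.685). At 6 d the medians were 0.08 for complexes II to V (0.438), -0.16 for the mitochondrial ribosome (0.0254) and -0.15 for the TCA cycle (0.21). The ribosomal proteins had 0.27 (1.11e-09) at 6 d, and -0.08 after quantile normalization. The heat shock chaperones HSPD1 (-0.46) and HSPE1 (-0.80) of the mitochondrial matrix fell as well.

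Other lists moved less or in both directions in 1% oxygen. CDKN1A, the cell cycle inhibitor p21, rose by 1.16 and GDF15 by 0.44, with 3 of 12 p53 targets up (camera adjusted p 0.115). The cytokeratins KRT8 (1.29) and KRT18 (0.91) rose and EPCAM fell (-0.35) among 7 epithelial and stromal markers, whose median (-0.04) and mean (0.38) differed in sign (camera adjusted p 0.00318, 0.251 with an estimated correlation). BST2 (-0.70) and IFITM3 (-0.81), antiviral proteins of the interferon response, fell, while their list did not pass (camera adjusted p 0.238). NQO1, a quinone reductase, fell (-0.47), and so did PSAT1, of serine synthesis (-0.46). TET3, a DNA demethylase that needs oxygen and 2-oxoglutarate, rose (0.72) as 1 of 5 such genes to do so. NEAT1, a nuclear RNA, rose (0.90), as did MALAT1 (0.43), both from the list of 8 nuclear-retained RNAs kept as a sign of RNA quality (camera adjusted p 0.0536). That list changed direction with time: its median was -0.27 at 6 h (camera adjusted p 7.65e-05, 0.00432 with an estimated correlation), -0.22 at 24 h (0.0984, 0.194), 0.55 at 3 d (0.000197, 0.00576) and 0.20 at 6 d (0.0254, 0.0591). Averaged over time, the camera test did not pass for S phase (0.727), G2 phase and mitosis (0.978), the ATF4 response (0.829), the chaperones of the endoplasmic reticulum (0.239), the NRF2 response (0.238) or iron handling (0.238). Nor did it pass for immediate early and heat shock genes (0.784), oxygen sensing (0.784), lipid storage and oxidation (0.988), peroxisomes (0.225), histones (0.532) or myeloid and lymphoid markers (0.517). Such averages can hide changes at single times. The S phase median was 0.18 at 6 h (camera adjusted p 6.38e-07), -0.83 at 3 d (5.08e-05) and 0.205 at 6 d (0.00012). At 24 h the ATF4 median was -0.378 (7.36e-06) and the NRF2 median -0.286 (2.68e-05).

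In total 3339 of 10625 genes passed the limma test averaged over time, 1317 higher and 2022 lower in 1% oxygen. Without the shallow library 5211 passed, 2459 higher and 2752 lower, of which 3304 were in the first set in the same direction. After rescaling to TPM 2726 passed, 1975 higher and 751 lower, so the excess of falls depended on the scale of the values. TPM divides by each library's total FPKM, which differed between libraries. The total was 1171415 in replicate 3 of 21% oxygen at 24 h, and 780267 and 900700 in replicates 1 and 2. In replicate 3 of 21% oxygen at 6 d the small RNA gene RNU6-69 alone held 26.3% of the total. Leaving out the shallow library made the 10 average falls named by the rule smaller, to unequal degrees, and all 10 passed the test both ways. The readthrough BLOC1S5-TXNDC5 went from -1.34 to -1.20 and MS4A4A from -1.24 to -1.12, while ZNRD1, a subunit of RNA polymerase I, went from -1.31 to -0.77, GNB1L from -1.21 to -0.84, FABP5, a fatty acid carrier, from -1.20 to -0.86, MS4A3 from -1.20 to -0.88, LSM10 from -1.16 to -0.66, TIMM10, of mitochondrial import, from -1.14 to -0.61, SSSCA1 from -1.10 to -0.65 and CISD1, an iron-sulfur protein of mitochondria, from -1.08 to -0.71.

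**Figure D1:**
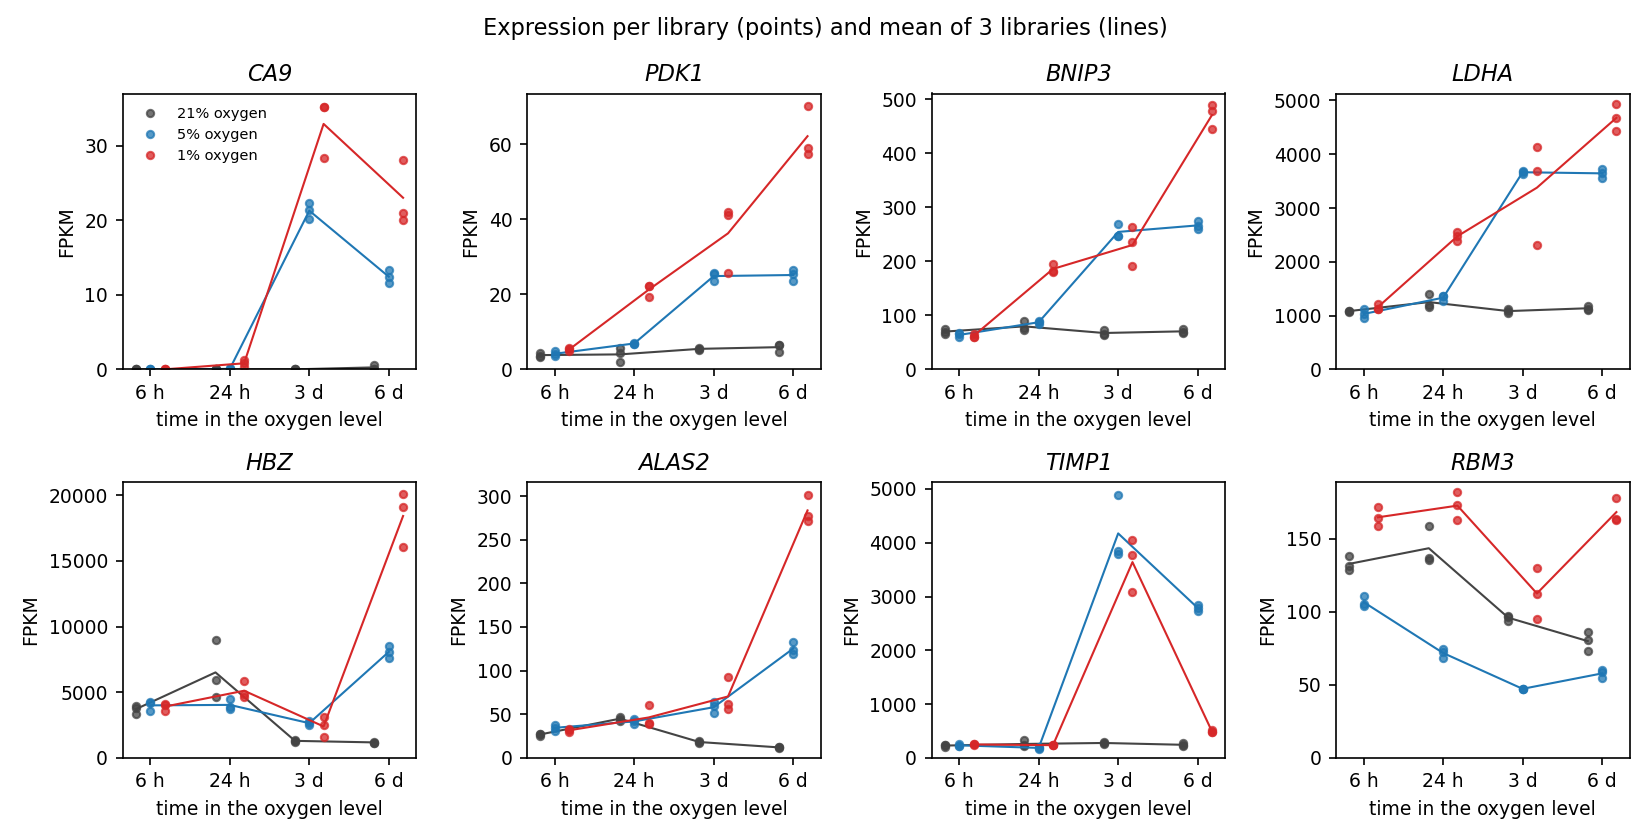
FPKM of 8 genes by time (x axis) in 21%, 5% and 1% oxygen, with a point for each library and lines through the means of 3 libraries. CA9, PDK1, BNIP3 and LDHA rose between 6 h and 6 d in low oxygen; HBZ and ALAS2 stood highest in 1% oxygen at 6 d, TIMP1 in 5% oxygen at 3 d, and RBM3 was lower in 5% oxygen than in 1% at every time.

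The response to 1% oxygen depended on time. At 6 h no gene passed the limma test, with 351 of 10625 at an unadjusted p under 0.05. That is a smaller share than the 0.05 that p-values give on average without any effect. The shallow library is in neither group but sets the pooled spread: the SE of RBM3 at 6 h was 0.0844 with it and 0.0688 without it. The count of 0 therefore does not show that no gene changed. Without that library 10 genes passed (8 higher, 2 lower), with 1157 at an unadjusted p under 0.05. Named after their values were seen, those 10 were EGLN3 (0.62), BHLHE40 (0.49), the replication helicase genes MCM5 (0.36) and MCM7 (0.30), ID1 (0.41), DUSP3 (0.58), MYEOV (0.51) and PDSS2 (0.47), which were higher, and the chaperone genes HSPA1A (-0.68) and CHORDC1 (-0.47), which were lower. The 22 glycolysis genes had a median of 0.15 at 6 h (camera adjusted p 3.11e-07, 0.19 with an estimated correlation) and the 28 other hypoxia-induced genes 0.02 (camera adjusted p 0.439). The 260 genes that rose at least 2-fold at 24 h, with a median of 1.31 there, had a median of 0.0315 at 6 h, beside 0.0466 for all genes. In simulated data of the same size, with the same spread in all libraries, the test at 6 h found 89.1% of 4-fold, 56.1% of 2-fold and 25.7% of 1.5-fold changes.

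At 24 h in 1% oxygen, 1723 genes passed, 697 higher and 1026 lower, and 4103 did without the shallow library. P4HA1 (1.75), ALDOC (1.93), PFKFB4 (2.14) and PDK1 (2.23) were up, and the glycolysis list had a median of 0.57, with 13 of 22 genes higher (15 adjusted over the list alone; camera adjusted p 2.93e-17, 0.0153 with an estimated correlation). The largest rises were in genes at low levels in 21% oxygen: GP1BB, a platelet receptor subunit that shares sequence with the readthrough transcript of SEPT5, went from 4.449 ± 3.15 to 90.09 ± 43 FPKM (SD, n = 3), the early response gene IER2 from 6.019 ± 2.2 to 53.2 ± 7.54, the phosphatase DUSP1 from 0.8124 ± 0.665 to 12.44 ± 2.05, and SDHAF1, an assembly factor of complex II, had a log2 difference of 2.70. In 21% oxygen itself IER2 and SDHAF1 were among the largest rises from 6 h to 3 d, and GP1BB from 6 h to 6 d. DUSP1 was not among the genes named there. Of 70 cytosolic ribosomal protein genes 66 were lower (median -0.67, camera adjusted p 2.82e-33), as were 30 of 44 of complex I and 26 of 39 of complexes II to V, NDUFB1 (-1.23) and ATP5I (-1.21) among the largest falls. With an estimated correlation each of these 3 lists had an adjusted p of 0.187. With a library left out the ribosomal protein median lay between -0.865 and -0.411. After quantile normalization the median of the 3 lists together was -0.142. After rescaling to TPM 88 of all genes were lower, fewer than the lower members counted in these lists. Without replicate 3 of 21% oxygen at 24 h the count of genes was 644, and without replicate 3 of 1% it was 1010. Quantile normalization gave 1103 genes (693 higher, 410 lower), and rescaling to TPM gave 2374 (2286 higher, 88 lower) and put the median of all genes at 0.386 where the main scale gave -0.00396.

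At 3 d in 1% oxygen, 5649 genes passed, 1791 higher and 3858 lower, and 5704 without the shallow library, 2675 higher and 3029 lower, with 4078 genes shared in direction. The shallow library shifted the median of all genes to -0.318, and it was -0.0146 without it, so falls at 3 d are given both ways. CA9 rose most. ANGPTL4, which restrains lipid uptake, rose from 0.1922 ± 0.181 to 36.09 ± 23.2 FPKM (SD, n = 3), and the skin secretory protein gene DMKN from 0.05193 ± 0.0899 to 28.87 ± 7.92. The keratin KRT8 rose from 367.5 ± 17.6 to 3510 ± 708 FPKM (SD, n = 3). HSPA5, the main chaperone of the endoplasmic reticulum, rose by 1.18, and the stress factor DDIT3 (CHOP) by 2.49. Of 28 genes of ribosome biogenesis all 28 fell (27 without the shallow library; median -1.15, and -0.999 without it; 28 adjusted over the list alone; camera adjusted p 8.24e-11, 0.0253 with an estimated correlation). Of 28 S phase genes 22 fell (21 without the shallow library), MCM3 (-1.06, -1.14 without it) and CDC45 (-1.10, -0.98) among them (median -0.83, and -0.62 without it; camera adjusted p 5.08e-05, 0.0742 with an estimated correlation). Other lists moved at the same time: the 8 nuclear-retained RNAs, kept as a sign of RNA quality, had a median of 0.55 (camera adjusted p 0.000197; 0.44 without the shallow library) and the 7 epithelial and stromal markers 0.98 (camera adjusted p 1.37e-05, 0.0727 with an estimated correlation; 1.05 without the shallow library). The steepest falls of single genes shrank without that library: IFI30, a lysosomal reductase, went from -4.19 to -2.53, NDUFB7 of complex I from -3.58 to -1.05, MRPS12 from -3.55 to -1.49 and SKP2, which drives entry into S phase, from -3.53 to -1.99.

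At 6 d in 1% oxygen, 1155 genes passed, 620 higher and 535 lower, 3164 without the shallow library (1464 higher, 1700 lower) and 749 without replicate 1 of 21% oxygen at 6 d. The red cell genes stood out: ALAS2 rose by 4.45, HBZ by 3.96, SLC4A1 by 3.87 and the embryonic globin HBE1 by 2.84 (each adjusted p at most 5.78e-15). Of 21 globin and erythroid membrane genes 17 rose and none fell (median 1.84, camera adjusted p 2.18e-30, 3.28e-06 with an estimated correlation), 18 adjusted over the list alone. The factor GATA1, which drives globin genes, rose by 0.60, NFE2 by 0.64, and GATA2 fell (-0.63). The list of erythroid transcription factors did not pass at this time (median 0.15, camera adjusted p 0.252). The metallothionein MT1G rose by 3.98. DMKN rose from 0.0506 ± 0.0455 to 40.45 ± 6.03 FPKM (SD, n = 3). The largest falls were in BLOC1S5-TXNDC5, a readthrough of neighbouring genes (-3.40), the protease gene PLAU (-2.17), MS4A4A (-2.10) and ALDH1A1, which makes retinoic acid (-2.04). VIM, an intermediate filament, fell (-1.48).

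**Figure D2:**
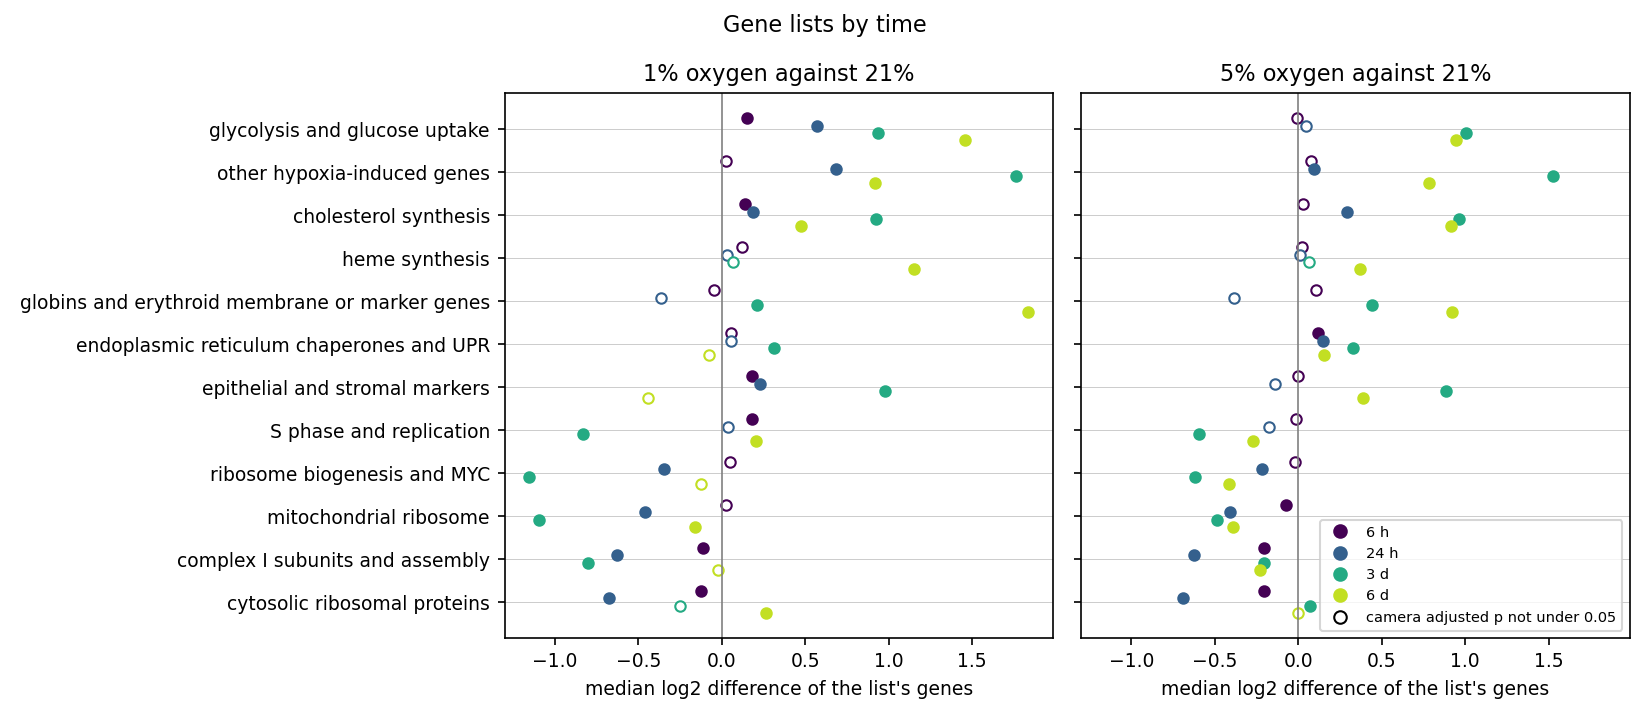
Median log2 difference from 21% oxygen at the same time (x axis) of 12 gene lists (y axis), for 1% oxygen on the left and 5% on the right, colored by time, with open points where the camera adjusted p was not under 0.05. The 21 globin and erythroid membrane or marker genes reached a median of 1.84 in 1% oxygen at 6 d; after quantile normalization the sign or camera direction turned for cytosolic ribosomal proteins (1% at 6 d, 5% at 3 d and 6 d) and, in 5% oxygen at 24 h, for ribosome biogenesis and the epithelial markers.

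A test of whether the difference between 1% and 21% oxygen varied among the 4 times passed for 4285 genes, and for 6721 without the shallow library. The smallest adjusted p values belonged to CA9 (1.56e-15), DMKN (2.94e-15), ALAS2 (7.06e-15), STAT5A (1.1e-14), a transcription factor of cytokine signaling, and TIMP1 (1.56e-14), an inhibitor of matrix proteases. TIMP1 stood at 3640 ± 497 FPKM (SD, n = 3) at 3 d in 1% oxygen against 276.3 ± 25 in 21%, and at 491.7 ± 26 against 242.4 ± 28.8 at 6 d. VIM was at 1686 ± 133 against 852.5 ± 26.4 at 3 d and at 244.6 ± 5.37 against 685.2 ± 12.6 at 6 d. DDIT3, KRT8, BNIP3 and KRT18 were the others of the 10.

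The second question was what the milder level of 5% oxygen changed. Averaged over time, 2573 genes passed against 21% oxygen, 979 higher and 1594 lower, and 5146 without the shallow library, which is in neither group but sets the spread of the fit. After rescaling to TPM 1885 passed, 1374 higher and 511 lower. The HIF targets led again: EGLN3 rose by 1.77 (SE 0.0944, adjusted p 5.41e-14), P4HA1 by 1.58, ANKRD37 by 1.53, BHLHE40 by 1.51 and BNIP3 by 0.95. PDK1 passed as well, with 25.17 ± 1.45 FPKM (SD, n = 3) at 6 d against 5.919 ± 1.19 in 21%. Of the 22 glycolysis genes 19 rose (median 0.57, camera adjusted p 1.12e-24, 0.00188 with an estimated correlation; 19 adjusted over the list alone), LDHA (0.86), PGK1 (0.64), SLC2A1 (0.61), SLC2A3 (0.82) and HK2 (0.55) among them. Of 28 other hypoxia-induced genes 21 rose (median 0.61, camera adjusted p 1.12e-24, 0.000639 with an estimated correlation), with VEGFA at 0.66, ADM at 1.27 and NDRG1 at 0.55. EPAS1 rose by 0.74, and HIF1A did not pass (adjusted p 0.998). Other large rises were in C19orf77 (1.70), the kinase-dead receptor EPHB6 (1.38), DLK1 (1.30), a ligand related to Notch ligands, and ACSS2 (1.24), which makes acetyl-CoA from acetate. Of 25 cholesterol synthesis genes 21 rose, FDPS (0.72) and HMGCS1 (0.96) with them (median 0.56, camera adjusted p 2.05e-25, 0.00188 with an estimated correlation; 23 adjusted over the list alone). SCD rose by 0.58 and TXNIP by 0.60.

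The red cell genes were higher in 5% oxygen too, with ALAS2 at 1.28 (SE 0.0722), HBZ at 0.82, SLC4A1 at 1.13, TFRC at 0.47, HBG1 at 0.28 and HBA1 at 0.55. Of 21 globin and membrane genes 8 rose (median 0.26, camera adjusted p 5.36e-06, 0.0331 with an estimated correlation; 9 adjusted over the list alone). Here too the average came from the later times, the median being 0.10 at 6 h, -0.38 at 24 h (camera adjusted p 0.105, 4 genes lower), 0.44 at 3 d and 0.92 at 6 d. The nuclear-retained RNAs had medians of -0.14, -0.26, 0.43 and 0.13 at these times (camera adjusted p 0.0451, 0.0207, 0.00688 and 0.0155; 0.427, 0.233, 0.0199 and 0.0381 with an estimated correlation). Chaperones of the endoplasmic reticulum were up as single genes, 8 of 20, HSPA5 (0.53) and HSP90B1 (0.42) first, though the list's camera adjusted p of 1.14e-05 became 0.0782 with an estimated correlation. KRT8 (1.34), KRT18 (1.16) and KRT19 (0.88) rose among 7 epithelial and stromal markers (median 0.27, camera adjusted p 4.12e-07, 0.0331 with an estimated correlation). MYC fell (-0.30) with 20 of 28 ribosome biogenesis genes (median -0.33, camera adjusted p 4.08e-10, 0.0331 with an estimated correlation; 21 adjusted over the list alone). The mitochondrial genes were lower as single genes in 5% oxygen as in 1%: 28 of 44 of complex I (median -0.32), 22 of 39 of complexes II to V (-0.26), 40 of 58 of the mitochondrial ribosome (-0.36) and 12 of 21 of the TCA cycle (-0.25), and so were 28 of 70 ribosomal protein genes (-0.20, but -0.00165 at 6 d). Their camera adjusted p values of 1.98e-09, 2.12e-07, 9.01e-14, 2.31e-05 and 2.71e-08 became 0.229, 0.282, 0.188, 0.272 and 0.467 with an estimated correlation. The same was seen for fatty acid synthesis (7.03e-05 and 0.188), heme synthesis (0.021 and 0.198), immediate early and heat shock genes (0.0205 and 0.198), megakaryocyte markers (0.0284 and 0.128) and the demethylases and hydroxylases that need 2-oxoglutarate (0.0311 and 0.453). Of 28 S phase genes 12 fell, MCM3 (-0.36) first (camera adjusted p 7.03e-05, 0.0838 with an estimated correlation). Lower single genes included FABP5 (-0.90), TCN1, a binder of vitamin B12 (-0.85), the myeloid surface proteins MS4A3 (-0.84) and CD33 (-0.82), PLAU (-0.81) and PYCARD, the adaptor of inflammasomes (-0.80).

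By time, no gene passed the limma test at 6 h in 5% oxygen, with 280 at an unadjusted p under 0.05, again a smaller share than 0.05. None passed without the shallow library either, with 1027 at an unadjusted p under 0.05 there. At 24 h 997 genes passed, 254 higher and 743 lower, and 2994 without the shallow library. P4HA1 rose by 0.90 and EGLN3 by 1.02 at that time, while the glycolysis list had a median of 0.05 (camera adjusted p 0.407). Of 70 cytosolic ribosomal protein genes 69 were lower at 24 h (median -0.69, camera adjusted p 7.38e-48, 0.233 with an estimated correlation). With a library left out that median lay between -0.886 and -0.443. The count of 69 does not hold without replicate 3 of 21% oxygen, where 47 genes passed in all. Nor does it hold after rescaling to TPM, where 12 of all genes were lower. The RNA-binding protein genes RBM3 (-0.99) and SLIRP (-0.96) and the metallothionein MT2A (-1.28) were lower as well. The count at 24 h rested on single libraries: without replicate 3 of 21% oxygen it was 47, and it was 88 without replicate 3 and 315 without replicate 2 of 5% oxygen. Quantile normalization gave 293 (199 higher, 94 lower), and rescaling to TPM gave 1721 (1709 higher, 12 lower) with a median of all genes of 0.364 where the main scale gave -0.0243. At 3 d 2319 genes passed, 877 higher and 1442 lower (4775 without the shallow library). CA9 rose by 4.48, and TIMP1 went from 276.3 ± 25 to 4174 ± 625 FPKM (SD, n = 3). STAT5A (-1.80) and the histone genes HIST1H1E (-2.48), HIST1H3J (-2.21) and HIST1H1B (-2.11) fell, histone copies being close in sequence. At 6 d 1575 genes passed, 769 higher and 806 lower (3927 without the shallow library; 1035 after rescaling to TPM, 776 higher and 259 lower; 2325 without a filter, 1530 higher and 795 lower). The chemokine CCL2 rose by 4.03, TIMP1 by 3.52, BTG2, an inhibitor of proliferation, by 3.46 and ALAS2 by 3.28, and MS4A4A (-2.12), MS4A3 (-1.77), STAT5A (-1.77) and TNFRSF8, known as CD30 (-1.70), fell. The difference between 5% and 21% oxygen varied with time for 1536 genes (4455 without the shallow library). TIMP1 (9.43e-17), KRT8 (9.43e-17), KRT18 (2.16e-16), CA9 (3.37e-15) and DDIT3 (5.6e-15) had the smallest adjusted p values.

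**Figure D3:**
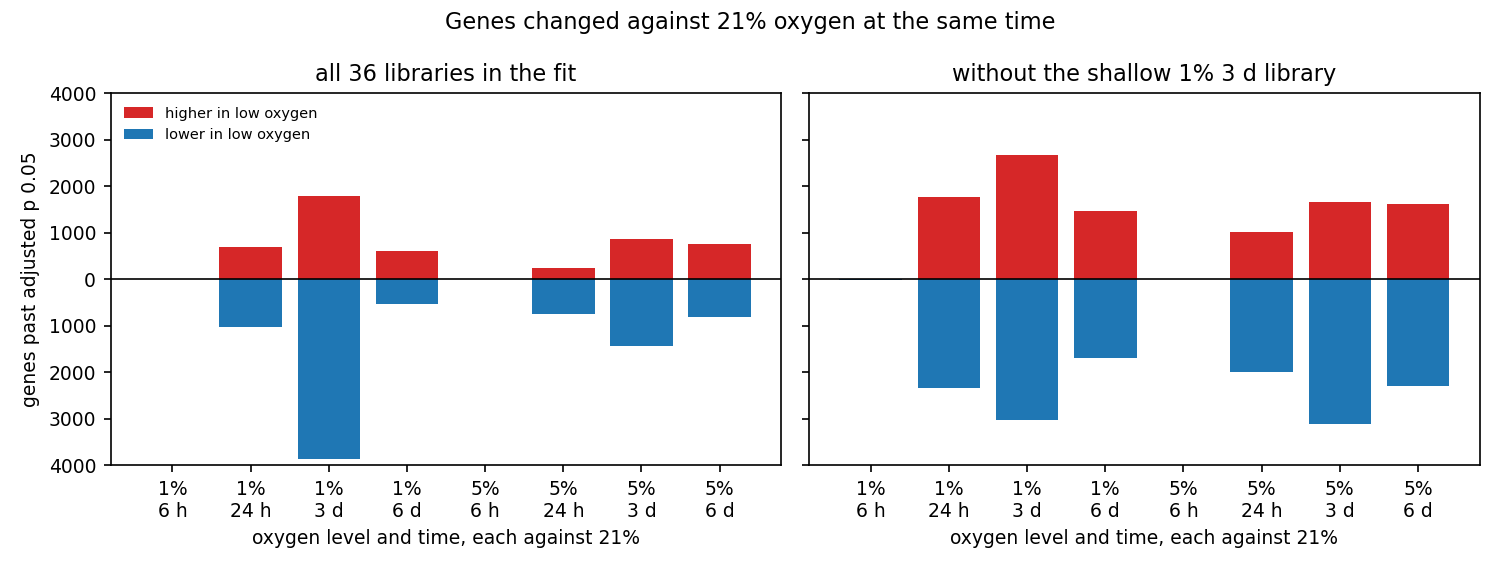
Number of genes past an adjusted p of 0.05 (y axis) in 1% and 5% oxygen against 21% at each time, higher genes above and lower genes below the line, with all 36 libraries on the left and without the shallow library on the right. In 1% oxygen at 3 d the lower genes numbered 3858 with that library and 3029 without it.

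The third question was how the responses to 1% and 5% oxygen compared. Between them, averaged over time, 469 genes differed, 307 higher and 162 lower in 1% oxygen, and 1504 without the shallow library, which is replicate 3 of 1% at 3 d, 943 without replicate 1 and 1015 without replicate 2 of that group. Quantile normalization gave 793, 384 higher and 409 lower. PDK1 was higher in 1% oxygen (0.89, SE 0.0993, adjusted p 1.19e-06), as were BNIP3 (0.43), CA9 (0.54) and LDHA (0.32). Of the 22 glycolysis genes 14 were higher in 1% oxygen (median 0.21, camera adjusted p 1.54e-19, 0.0152 with an estimated correlation; 15 adjusted over the list alone), and of 28 other hypoxia-induced genes 9 were higher and 1 lower (median 0.19, camera adjusted p 5.15e-10, 0.031 with an estimated correlation). RBM3, an RNA-binding protein induced by cold, had the smallest adjusted p: it was higher in 1% than in 5% oxygen by 1.16 (adjusted p 5.21e-17), with 168.4 ± 8.54 FPKM (SD, n = 3) in 1%, 80 ± 6.32 in 21% and 57.87 ± 2.75 in 5% at 6 d. DMKN (1.39), the cytokine TNFSF9 (0.83) and AQP10 (0.77) were also higher. Heme synthesis had 4 of 13 genes higher, FECH (0.44) first (camera adjusted p 8.7e-05, 0.031 with an estimated correlation). S phase had 6 of 28 genes higher, MCM5 (0.32) first (camera adjusted p 2.97e-07, 0.031 with an estimated correlation). Lower in 1% oxygen were the nuclear receptor NR4A1 (-1.02), the pore-forming PRF1 (-0.75), the growth factor IGF1 (-0.68) and the chaperones HSPA5 (-0.40) and HSP90B1 (-0.33), with 5 of 20 genes of the endoplasmic reticulum list (camera adjusted p 3.85e-07, 0.031 with an estimated correlation). The immediate early and heat shock list was lower too, 5 of 20 genes, HSP90AA1 (-0.15) and DNAJB1 (-0.21) first (median -0.15, camera adjusted p 3.91e-05, 0.031 with an estimated correlation). The lists of cell type markers and RNA quality moved as well, with calls that ended with an estimated correlation: the epithelial and stromal markers (median -0.20, camera adjusted p 0.00323, then 0.217), the nuclear-retained RNAs (0.11, 0.0473, then 0.11), the megakaryocyte markers (0.19, 0.0473, then 0.159) and the globin and membrane genes (0.18, 0.000744, then 0.11).

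The average responses to 1% and 5% oxygen shared 759 rises and 1225 falls, with 7 genes called in opposite directions. Without the shallow library they shared 1542 rises and 2273 falls, with 33 in opposite directions, and after rescaling to TPM 1108 rises and 345 falls. Independent lists of these sizes would share 121 rises and 303 falls, and in 20 simulated data sets with no effect and the same controls 0 rises and 0 falls were shared. Without an effect the adjusted test is built to pass few genes, so that 0 does not measure what the shared controls add to the overlap. Across genes, which are not independent replicates, the log2 differences had a correlation of 0.787, beside 0.503 in the simulated data, where the shared 21% libraries alone produce it. With the 12 controls divided into sets of 6, 20 ways, the correlation averaged 0.667 (0.629 to 0.692). With the part from shared controls removed, the effect at 5% was 0.696 of that at 1% (jackknife SE 0.195), and 0.828 without the shallow library.

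The fourth comparison followed the 21% cultures over time, as the background on which the oxygen comparisons stand. The labels state a passage at 3 d, so effects of time and of the passage cannot be separated at the later times. This limit also holds where the oxygen differences are compared between times. Between 6 h and 24 h 14 genes passed, 5 higher and 9 lower. Sterol and fatty acid genes were lower at 24 h: HMGCS1 (-0.88) and the desaturases FADS1 (-0.83) and SCD (-0.58), and 4 of 25 cholesterol genes fell (10 adjusted over the list alone; camera adjusted p 1.69e-13, 0.077 with an estimated correlation). DHRS3, a retinal reductase (1.31), ALAS2 (0.72) and the amino acid response genes PCK2 (0.55) and ASNS (0.43) were higher. That count was 2 without replicate 2 and 3 without replicate 3 at 6 h, 166 without replicate 1 (83 higher, 83 lower) and 9 without replicate 2 at 24 h, and was 257 without the shallow library (192 higher, 65 lower), so its balance of directions is open. At 3 d 489 genes differed from 6 h, 363 higher and 126 lower (1918 without the shallow library, 196 without replicate 1 at 6 h, and 271, 272 and 268 without replicates 1, 2 and 3 at 3 d). Cholesterol synthesis was higher by then, with 13 of 25 genes, INSIG1 (2.47) among them (median 0.53, camera adjusted p 4.02e-22, 0.00402 with an estimated correlation; 19 adjusted over the list alone). HBZ (-1.52) and HBA2 (-1.38) were lower. At 6 d 1182 genes differed, 838 higher and 344 lower (3109 without the shallow library, 575 without replicate 1 at 6 h, and 754, 756 and 696 without replicates 1, 2 and 3 at 6 d). INSIG1 reached 3.87 and the cholesterol list had 17 of 25 genes higher (camera adjusted p 1.17e-18, 0.0102 with an estimated correlation). Of 21 globin and erythroid membrane genes 10 were lower at 6 d than at 6 h, HBZ (-1.66) and HBA2 (-1.62) most (median -0.85, camera adjusted p 1.42e-11, 0.00292 with an estimated correlation; 13 adjusted over the list alone), and ALAS2 fell (-1.10). The 8 nuclear-retained RNAs, kept as a sign of RNA quality, were lower with them, by a median of -0.48 at 3 d (camera adjusted p 3.9e-07, 0.00031 with an estimated correlation) and -0.53 at 6 d (9.16e-05, 0.00292). The 4 myeloid and lymphoid markers had a median of 0.50 at 3 d (camera adjusted p 0.0207, 0.101 with an estimated correlation) and 0.56 at 6 d (0.0422, 0.234), and the 7 epithelial and stromal markers 0.26 at 3 d (0.000736, 0.169) and 0.27 at 6 d (0.0882, 0.495). The higher red cell genes in low oxygen at 6 d stood against controls in which several had fallen: HBZ in 21% oxygen was 3714 ± 334 FPKM (SD, n = 3) at 6 h and 1175 ± 51.6 at 6 d. The small RNA gene RNU86 and GP1BB with its readthrough SEPT5-GP1BB had the largest rises, and the plakophilin PKP3 rose by 3.18. ATF5, a stress-response factor, fell (-1.33).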

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

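Of the tests in this part, those on the shallow library, on background reads and on the difference between 1% and 5% oxygen at single times were chosen only after the result was seen. The first results are here because the difference from 21% oxygen was unequal among the times: 4285 genes varied with time for 1% oxygen and 1536 for 5%. For CA9 the difference at 1% was 5.08 at 3 d and 4.26 at 6 d, and for ALAS2 4.45 at 6 d. Of 100 splits of the libraries only the real one reached each count: the highest other split gave 2901 genes for 1% oxygen and 1196 for 5%. The splits swapped labels within single times, which can make a steady oxygen effect vary with time. They are therefore a rough reference.

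The next result is here because the difference between 1% and 5% oxygen changed with time in the 50 glycolysis and HIF target genes. Their median difference from 21% oxygen was 0.627 in 1% and 0.0843 in 5% at 24 h, and 1.42 and 1.36 at 3 d (1.56 in 1% without the shallow library). The ratio of the medians at 24 h was 0.134 (0.0358 to 0.178 with a library left out). At 6 h the medians were 0.0979 and 0.0375, and at 6 d 1.04 and 0.902. The glycolysis genes alone were higher in 1% than in 5% oxygen at 6 d (median 0.372, camera adjusted p 1.86e-08). The other hypoxia-induced genes had 0.191 there (0.14). Set against 24 h, the difference between the levels changed by -0.469 at 6 h and -0.197 at 6 d (camera adjusted p 1.62e-39 and 1.78e-08, 0.000126 and 0.0446 with an estimated correlation). From 24 h to 3 d the difference between the levels changed by a median of -0.605 (camera adjusted p 2.91e-09 over 3 tests, 0.0446 with an estimated correlation, 20 genes lower), and by -0.419 without the shallow library. The tests argue against that library as the whole cause, since without it the ratio of the 5% to the 1% median at 3 d was 0.874 (0.834 to 0.935 with a further library left out), and against background reads, since among 27 members with a mean of at least 20 FPKM the ratio was 0.984 (0.844 to 1.13). Over all genes the effect at 5% relative to 1% did not rise: it was 0.825 at 24 h and 0.364 at 3 d (0.687 and 0.655 without the shallow library). That measure is taken from how the 5% and 1% differences of all genes vary together, not from medians. It therefore cannot show whether the pattern is particular to these 50 genes. The pattern was found in these data, and no biological explanation was tested.

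The last result is here because of a signal in the transcript table, which the comparisons do not use. A single transcript had 250964 FPKM in replicate 3 of 1% oxygen at 6 h, 24.7% of that library's total, and was listed at 0 in the other 35 libraries. Its name was not found among the reference names used here, and no explanation for it was tested.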

How the results depend on the processing

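Leaving the shallow library out of the whole fit and correcting for GC content and length are the tests chosen only after the data were seen, as are all those on 1% against 5% oxygen at single times. Where the cause of a change is not stated, the cause was not tested. Counts below are of genes.

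Adding a fold of at least 2 by construction lowers the counts: for 1% against 21% oxygen to 293 at 24 h, 2637 at 3 d, 301 at 6 d and 101 averaged; for 5% to 54, 441, 362 and 71; for 1% against 5% averaged to 3; for 21% against 6 h to 2 at 24 h, 93 at 3 d and 389 at 6 d; and for 1% against 5% at single times to 0 at 6 h (5 in limma without the fold), 13 at 24 h, 1350 at 3 d and 168 at 6 d. The fold limit turned the larger side from lower to higher for 1% at 24 h (260 higher, 33 lower) and averaged (74 and 27), for 5% at 24 h (52 and 2), 3 d (333 and 108), 6 d (291 and 71) and averaged (69 and 2) and for 21% at 24 h (2 and 0), and from higher to lower for 1% against 5% at 6 d (28 and 140).

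A fit on the compared groups only gave, for 1% against 21%, 1 at 6 h, 1368 at 24 h (867 higher and 501 lower, 822 shared with the main 1723), 818 at 3 d and 3131 at 6 d (1543 higher, 1588 lower); for 5%, 2 at 6 h, 1 at 24 h, 4443 at 3 d, 5229 at 6 d and 5029 averaged; 288 for 1% against 5% averaged; 4063 varying with time for 5%; for 21% against 6 h, 0 at 24 h (14 in the limma fit of all groups), 1848 at 3 d and 3354 at 6 d; and for 1% against 5%, 2 at 6 h, 0 at 3 d and 2794 at 6 d. Such fits hold fewer samples.

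With the replicate number as a block (replicate block) the counts stayed within 1.5 times: 1661 for 1% at 24 h and 3279 averaged, except 1 for 1% against 5% at 6 h. The numbers did not pair the libraries, as in 0 of 15 comparisons did every pair exceed a correlation of 0.1. Without a filter 1% against 5% gave 1 at 6 h and 2210 at 6 d (564 higher, 1646 lower), and 5% at 6 d had 1530 higher and 795 lower.

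Quantile normalization gave 1103 for 1% at 24 h, 293 for 5% at 24 h, 793 for 1% against 5% averaged, 32 and 848 for 21% at 24 h and 3 d, and 8 and 124 for 1% against 5% at 6 h and 24 h. TPM gave 1721 for 5% at 24 h, 1035 at 6 d, 2436 varying with time, 252 for 1% against 5% averaged, 24 for 21% at 24 h, and 0, 47 and 579 for 1% against 5% at 6 h (5 in limma), 24 h and 6 d. For 1% at 24 h TPM gave 2374. TPM turned the larger side from lower to higher for 1% at 24 h (2286 higher, 88 lower) and averaged (1975 and 751; 1317 and 2022 on the main scale), 5% at 24 h (1709 and 12), at 6 d (776 and 259) and averaged (1374 and 511), 1% against 5% at 3 d (2394 and 865) and the shared genes (1108 rises, 345 falls), and from higher to lower for 1% against 5% at 6 d (110 and 469). Quantile normalization turned it for 1% at 24 h (693 and 410), for 5% at 24 h (199 and 94) and 6 d (1146 and 1095) and for 1% against 5% averaged (384 and 409), at 6 h (3 and 5) and at 6 d (590 and 639). TPM moved the median log2 difference of all genes by over 0.1: for 1% from -0.00396 to 0.386 at 24 h and from -0.0718 to 0.0456 averaged; for 5% from 0.00317 to 0.127, -0.0243 to 0.364, -0.0979 to -0.231 and -0.0616 to 0.055 from 6 h to 6 d and from -0.039 to 0.0841 averaged; for 21% at 24 h from 0.0335 to -0.194; and for 1% against 5% from 0.0391 to -0.061 at 6 h, -0.234 to 0.00616 at 3 d and 0.0331 to -0.112 at 6 d. Quantile normalization moved it from -0.318 to -0.0146 for 1% at 3 d and from -0.234 to 0.0233 for 1% against 5% at 3 d.

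Array weights gave, for 1%, 47 at 6 h, 4464 at 24 h, 4966 at 6 d, 5839 averaged and 7547 varying with time; for 5%, 3499, 5786 and 5695 from 24 h to 6 d, 5989 averaged and 6164 varying with time; 2216 for 1% against 5% averaged; 287, 3077 and 4295 for 21% from 24 h to 6 d; and 458, 1843, 2030 and 4457 for 1% against 5% from 6 h to 6 d. They turned the larger side for 1% at 6 d (2224 higher, 2742 lower) and 1% against 5% at 3 d (1188 and 842). Without the shallow library the counts were, for 1%, 10 at 6 h, 4103 at 24 h, 3164 at 6 d, 5211 averaged and 6721 varying with time; for 5%, 2994, 4775 and 3927, 5146 averaged and 4455 varying with time; 1504 for 1% against 5% averaged; 257, 1918 and 3109 for 21%; 134, 313 and 2931 for 1% against 5% at 6 h, 24 h and 6 d; and 3815 shared by both responses where all libraries gave 1984. The larger side turned for 1% at 6 d (1464 higher, 1700 lower), 21% at 24 h (192 and 65) and 1% against 5% at 3 d (1760 and 1102). The GC and length correction gave 634 for 5% at 24 h. The effect at 5% relative to 1% lay between 0.57 (pseudocount 0.1) and 0.828 (without the shallow library), and between 0.541 and 0.828 with a library left out.

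Each library of the groups compared was left out in turn. For 1% this gave 0 to 0 at 6 h (limma, 351 at an unadjusted p under 0.05) and 644 (without 21% 24 h replicate 3) to 1913 at 24 h. It gave 4752 to 6998 at 3 d, 749 (without 21% 6 d replicate 1) to 976 at 6 d, 2966 to 5211 averaged and 3574 to 6721 varying with time. For 5% it gave 0 to 0 (280 at an unadjusted p under 0.05), 47 (without 21% 24 h replicate 3) to 1361, 1795 to 1999, 1100 to 1213, 2307 to 2628 averaged and 1275 to 1817 varying with time. For 1% against 5% averaged it gave 352 to 1504 (without 1% 3 d replicate 3). For 21% it gave 2 (without 6 h replicate 2) to 166 (without 24 h replicate 1), 196 to 403 and 575 to 1024, both lowest without 6 h replicate 1. For 1% against 5% at single times it gave 1 to 3, 39 to 55, 1968 to 6394 and 531 to 821. For 5% at 6 d (769 higher, 806 lower) each such fit had more higher than lower, and 1% against 5% at 6 d had more lower without 1% replicate 1 (409 and 412) or replicate 3 (243 and 288). Where a group keeps 2 libraries, the pooled spread covers it. These ranges do not cover the shallow library where it is in neither group, although it sets the pooled spread. Without that library 1% gave 10 at 6 h, 4103 at 24 h and 3164 at 6 d. For 5% the counts from 24 h to 6 d were then 2994, 4775 and 3927. Each of these lies above the range given here.

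The 278 single-gene values were of genes named by the rule or in the text. Many were named for a large difference past the threshold in these data, so few could reverse. A change of sign did not count where the value passed neither in the main fit nor in the alternative. On that count 0 reversed. Calls were lost for 22 with the smaller pseudocount, 21 without a filter, 43 in fits on the compared groups and 4 with the block. Losses were 14 after quantile normalization, 29 after TPM and 10 after the GC correction. Gained were 13 with array weights, 13 without the shallow library and 1 in fits on the compared groups. Of 4296 single-gene values with a library left out 224 lost their call and 2 gained one. Of 558 list results 188 lost their camera call with an estimated correlation and 94 with fry, which gained 22. Lost and gained were 6 and 6 with the smaller pseudocount, 28 and 28 without a filter, 27 and 10 with the stricter one, 17 and 13 in fits on the compared groups, 3 and 0 with the block, 50 and 31 after quantile normalization, 23 and 27 after TPM, 20 and 18 with array weights, 14 and 12 without the shallow library, 24 and 14 after the GC correction, and 126 and 73 of 5022 with a library left out. A reversal of a list result is a turn of its camera direction, and the median can keep its sign. After quantile normalization it did so for ribosome biogenesis (5% at 24 h, -0.217 in the main fit) and the TCA cycle (21% at 24 h, 0.168). The same held for ribosomal proteins (5% at 6 d, -0.00165, and 21% at 3 d, -0.238). Quantile normalization reversed 16. The medians became 0.0413 for iron handling and 0.0614 for G2 and mitosis (1% at 24 h); 0.0783 for G2 and mitosis, 0.0441 for NRF2, -0.00658 for ribosome biogenesis and 0.134 for epithelial markers (5% at 24 h); -0.0774, -0.115 and -0.135 for ribosomal proteins (1% at 6 d, 5% at 3 d and 6 d); -0.028 for glycolysis, 0.0193 for the TCA cycle, -0.0517 for NRF2 and -0.0028 for ribosomal proteins (21% at 24 h), -0.00286 for ribosomal proteins (21% at 3 d), and -0.00924 for the mitochondrial and -0.032 for the cytosolic ribosome (1% against 5% at 6 h). TPM reversed 5: G2 and mitosis to 0.34 (1%) and 0.323 (5%) and ATF4 to 0.21 (5%) at 24 h, and glycolysis to -0.137 and NRF2 to -0.109 (21% at 24 h). For 1% against 5% at 24 h, G2 and mitosis ranged from -0.0733 to 0.091 with a library left out, the latter without 1% 24 h replicate 3. In each library the unknown depth limits weakly expressed genes.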

Other observations

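Among the tests in this part, the scaling tests, the comparisons of 1% with 5% oxygen at single times and the choice of patterns were made only after the result was seen, while the test of CIRBP was set before its values were seen. Compared directly at 6 d, 1% and 5% oxygen differed for 915 genes, 501 higher and 414 lower in 1%. Which side had more genes depended on the processing: after rescaling to TPM 110 were higher and 469 lower, without a filter 564 and 1646, and after quantile normalization 590 and 639. The count was 2931 without the shallow library, 531 without replicate 3 of 1%, and 605 and 570 without replicates 2 and 3 of 5%. Red cell genes were higher in 1%: ALAS2 by 1.17, FECH by 1.06 and HBZ by 1.19. Of 21 globin and membrane genes 11 were higher (median 0.72, camera adjusted p 4.5e-11, 0.00308 with an estimated correlation; 13 adjusted over the list alone). Of 28 S phase genes 11 were higher, MCM4 (0.59) among them (median 0.38, camera adjusted p 1.96e-11, 0.00362 with an estimated correlation; 13 adjusted over the list alone). Lower in 1% were the filament genes VIM (-1.87), KRT8 (-1.70) and KRT18 (-1.71), the chaperone HSPA5 (-1.02), the sterol gene FDPS (-1.21) and the stress factor DDIT3 (-1.41). Of 7 epithelial and stromal markers 5 were lower (median -1.13, camera adjusted p 1.6e-14, 0.00308 with an estimated correlation), and of 25 cholesterol genes 12 (17 adjusted over the list alone; camera adjusted p 1.62e-11, 0.0381 with an estimated correlation). At 3 d 3890 genes differed, 1423 higher and 2467 lower in 1% (2862 without the shallow library, 1760 higher and 1102 lower, 1731 of them shared; 2394 higher and 865 lower after rescaling to TPM; 6394 without replicate 1 and also without replicate 2 of 1%, and 1968 without replicate 3 of 5%), and at 24 h 79 (313 without the shallow library, 39 and 48 without replicates 1 and 2 of 1%, 44, 44 and 46 without replicates 1, 2 and 3 of 5%). At 6 h 5 genes differed (134 without the shallow library, 1 without any replicate of 1% and 2, 2 and 3 without replicates 1, 2 and 3 of 5%), all named after their values were seen: RBM3 (0.62), the splicing factor SRSF5 (0.55) and the mitochondrial protease PMPCB (0.40) higher in 1%, and the chaperone partner CHORDC1 (-0.52) and the translation factor EIF4A2 (-0.41) lower.

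RBM3, a gene known to rise with mild cold, was lower in 5% than in 21% oxygen (-0.69) and higher in 1% (0.46). A difference in temperature between the incubators may explain it, and predicts the same for CIRBP, the other gene best known to rise with cold, whose values had not been seen. CIRBP was higher in 1% than in 5% oxygen by 0.715 (0.578 to 0.853 within 2 SE, adjusted p 1.14e-07, 0.66 without the shallow library), as predicted for the average. At single times its difference was 0.569 at 6 h (adjusted p 0.169), 0.532 at 24 h (0.076), 0.66 at 3 d (0.00132) and 1.10 at 6 d (2.53e-06). Against 21% oxygen averaged over time CIRBP moved the same way as RBM3, by 0.286 in 1% (adjusted p 0.00217) and -0.43 in 5% (2.48e-05). The genes also parted: in 1% against 21% oxygen CIRBP had 0.0161 at 24 h (adjusted p 0.966) and 0.0273 at 3 d (0.88; -0.212 without the shallow library), where RBM3 had 0.267 (0.0284) and 0.217 (0.0329). The gap between the genes was not tested. Oxygen level and incubator are confounded, temperature is not given in the sources used here, and both genes are also known to respond to low oxygen, so a response to oxygen remains open. The hypothesis was made from RBM3 in these same data.

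The ribosomal protein and respiratory chain genes, 153 in all, were lower at 24 h in both low oxygen levels. The median was -0.662 in 1% oxygen and -0.655 in 5%. Replicate 3 of 21% oxygen at 24 h may contribute, as these genes stood 1.0 above their mean over all libraries in it and 0.18 and 0.471 above in the other 2, but without it the medians were -0.431 (-0.574 to -0.287 with a further library left out) and -0.418 (-0.569 to -0.271), which argues against it as the whole cause, and after correction for GC content and length they were -0.514 (-0.642 to -0.352) and -0.473 (-0.596 to -0.314), which argues against that bias in the same way. After quantile normalization they were -0.142 and -0.119, between the bounds set for either answer, so the scaling of the values stays open. A lower supply of these transcripts in low oxygen was not tested apart from scaling. In 21% oxygen itself the lists were higher at 24 h than at 6 h. The medians were 0.311 for ribosomal proteins, 0.268 for complex I and 0.3 for complexes II to V. With a library left out they were as low as 0.0743, 0.0621 and 0.0696.

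Whether genes that rose at least 2-fold in 1% oxygen at 24 h had begun to rise at 6 h was asked in a test set before its result was seen: the 260 genes had a 6 h median of 0.0315, 0.0241 of that at 24 h (-0.139 to 0.152 with a library left out), and 152 were above 0, beside a median of 0.0466 for all genes. With all libraries the 6 h median did not exceed that of all genes. Its share of the 24 h median lay on both sides of 0 with a library left out, so a small early rise stays open.

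Other divisions of the same libraries were counted for each comparison. For the comparisons averaged over time, 1 of 100 splits, the real one, reached the count. The real counts were 3339 genes for 1% against 21% oxygen (highest other 1652), 2573 for 5% (183) and 469 for 1% against 5% (352). A share smaller than 1 of 100 cannot be shown with these splits, and no adjustment was made for testing several counts. For 3 libraries against 3 the 10 splits are too few. The real and highest other counts were 1723 and 0 for 1% at 24 h, 5649 and 2174 at 3 d, 1155 and 0 at 6 d, 997 and 0 for 5% at 24 h, 2319 and 0 at 3 d, 1575 and 0 at 6 d, 489 and 0 for 21% at 3 d against 6 h, 1182 and 0 at 6 d, and, for 1% against 5%, 5 and 1 at 6 h, 79 and 0 at 24 h, 3890 and 1824 at 3 d and 915 and 0 at 6 d, each real count reached by 1 split. At 6 h both 1% and 5% gave 0 genes in all 10 splits of the limma test, with 351 and 280 genes at an unadjusted p under 0.05. For 24 h against 6 h in 21% oxygen 2 splits gave at least the real 14, and the highest other gave 229, with replicate 1 at 6 h beside replicates 2 and 3 at 24 h, which points to a structure of the samples other than time.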
